A study of Fragaria vesca with 9 samples.

How the data were processed

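Fruits of Fragaria vesca, 26 days after anthesis, gave 9 poly(A) RNA libraries, 3 each from wild type and 2 mutant lines of FvMATE51, sequenced on an Illumina platform. The authors' table lists 34777 genes with 1 column of FPKM per library, scaled by the authors to gene length and to library size. It also gives coordinates, gene lengths, Swiss-Prot matches for 21003 genes and Pfam domains for 21409, and 771 of its genes are transcripts outside the annotation. The submitters' processing notes name fastp, HISAT2 2.2.1, StringTie 2.2.3 and featureCounts 2.0.6, without their roles or order. The genome build is not stated in the sources used here, so positions are given as listed. No reference genome was used here, so bias by GC content was not tested.

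Each FPKM value multiplied by the gene length was a whole multiple of 1 step per library, so fragment numbers could be recovered (100% of values within 0.02 of a whole number). Listed genes held 31587667 to 51649115 fragments per library, and 15054 to 15328 genes reached 1 FPKM. Replicates of a group differed beyond sampling noise (mean chi-square per gene 4.45 to 58.21, Pearson r across genes 0.9859 to 0.9948), so no library was a copy of another. For a gene at 0 in every library of a group, folds are lower bounds against 3 fragments in the library with the highest such floor. Floors cover counting error only.

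The tests were fixed before the data were examined. Values were analysed as log2(FPKM + 1) for the 15890 genes with at least 1 FPKM in at least 3 of 9 libraries. limma 3.58.1 in R 4.3.3 fitted 3 group means to all 9 libraries with a mean-dependent prior (limma-trend). Contrasts were the mean of both lines against wild type, each line against wild type, and line 2 against line 1. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided, and no covariate was used. Standard deviations are between libraries. Folds of named genes are ratios of mean FPKM. The log2 changes and the limit of at least 2-fold use FPKM + 1, which makes them smaller, most of all for genes near 0. Genes changed the same way in both lines were those called in each line with the same sign, compared with independent lists and with 100 simulations of unchanged groups that shared their controls.

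A set of 33 gene lists was fixed before the data were examined, as word patterns matched to the descriptions, among them markers of achenes, epidermis, vascular tissue, pollen and organelles. limma's camera tested each list with a preset correlation of 0.01, with adjustment over all lists of a contrast. It was repeated with an estimated correlation, and no call in any contrast held with it. For jasmonate and aroma volatiles, called between the lines, the estimated correlation was 0. Correlated members therefore do not account for the loss of those 2 calls, and its cause was not tested. Patterns also caught members outside a list's name: elongation factor 1-gamma among glutathione S-transferases, early nodulin-like proteins and a delta-7 desaturase in photosynthesis, quinone oxidoreductases in aroma volatiles, TMV resistance protein N in WRKY factors, DnaJ proteins and glutathione S-transferases in heat shock, TPL-binding and GATA factors in jasmonate, metal tolerance proteins in iron homeostasis, and inorganic pyrophosphatase in abscisic acid. The organelle list held nuclear subunits of organelle complexes.

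Named genes followed a fixed rule, limited to genes with a description or domain (12261 of those tested). It took the 12 largest rises and 12 largest falls of both lines against wild type with all 6 mutant values beyond the 3 wild type values, up to 4 members with the lowest adjusted p per list (for both lines against wild type and for line 2 against line 1), the 5 largest rises and falls of each line, the 6 of line 2 against line 1, and up to 5 MATE transporters. The report gives examples from these. The targeted gene was to be reported only if a description named it, which 0 did.

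The comparison of both lines with wild type was tested on simulated data with 50 genes planted per fold among 15890. Of these, 84% were recovered at 1.5-fold, 98% at 2-fold and 100% at 4-fold and 8-fold. The planted genes had a mean of at least 2 FPKM and changed alike in both lines. Recovery of genes below that mean, in single lines or between the lines was not tested. Of 15540 unchanged genes, 5 were called (0.03%). A planted list was found, and 0 of 30 random lists were called. The simulated genes varied independently of each other, while the estimated correlation among ribosomal protein genes was 0.55. False list calls that come from correlated members could therefore not appear in this test.

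Alternatives fixed in advance were pseudocounts of 0.1 and 0.01, no filter or a mean of at least 5 FPKM, median-of-ratios scaling, rescaling to the same FPKM sum (TPM), quantile normalization, the replicate number as a block, limma without trend, array weights, only the groups compared, at least a 2-fold change, and leaving out each library in turn. Limma voom on the recovered fragments, correction for gene length and leaving out wild type replicate 3 and line 1 replicate 2 were added after seeing the data. All libraries were used in the results.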

Results

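Gene expression was measured by sequencing polyadenylated RNA from fruits of woodland strawberry, Fragaria vesca, picked 26 days after anthesis. The 9 libraries formed 3 groups of 3: wild type, mutant line 1 and mutant line 2, the lines being 2 mutants of FvMATE51, a gene whose product the study describes as a protein of the vacuolar membrane. MATE transporters export organic compounds across membranes, and some plant members carry flavonoids into the vacuole. The values were fragments scaled to gene length and library size (FPKM) in 34777 listed genes. Fragments in listed genes numbered 42858627, 39187325 and 51649115 in wild type replicates 1, 2 and 3. Line 1 held 39172547, 31587667 and 40538911, and line 2 held 38130965, 39700768 and 39907761. Values are given below as the group mean ± SD in FPKM (n = 3 libraries per group). The labels do not say whether the replicates were separate plants, so the p-values measure only the spread between these samples, which may be technical.

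The 3 groups separated from each other on the first components of a principal component analysis, which held 41.5% and 39.1% of the variance. Component 3 held 7% and set wild type replicate 3 (19.4) and line 1 replicate 2 (14.8) apart from the other libraries, which lay between -12.7 and 4.3. The fragments outside the listed genes made up 1.78 to 3.71% of wild type libraries, 4.49 to 10.14% of line 1 libraries and 0.1 to 1.5% of line 2 libraries.

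**Figure D1:**
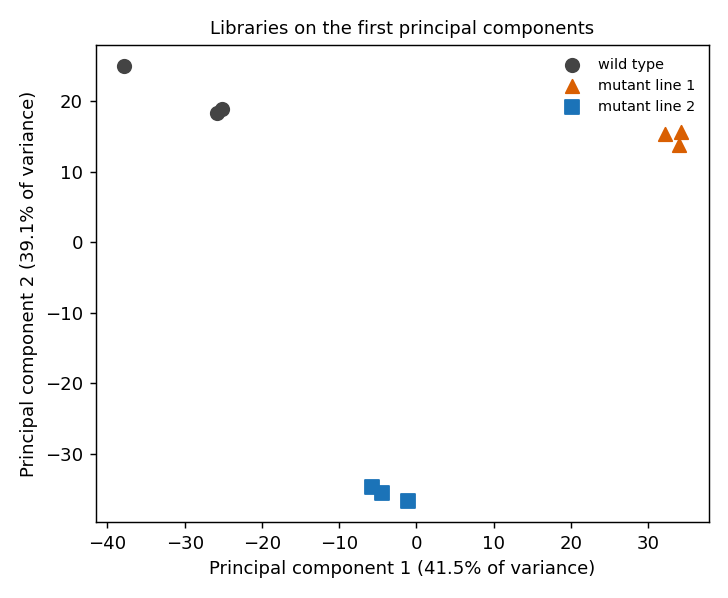
Each point is 1 of the 9 libraries, placed by its scores on principal components 1 (41.5% of the variance, horizontal axis) and 2 (39.1%, vertical axis), both without units. Wild type, line 1 and line 2 form 3 separate groups of 3 points, line 1 between 32.2 and 34.2 on component 1 and line 2 between -36.6 and -34.7 on component 2.

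The mutated gene itself could not be followed by name, since 0 of the gene descriptions contain MATE51, and its own level is not analysed here. Its family could: 62 listed genes carried a MATE description and 26 were tested. The mutated gene may be among them under another name, so a change in a member may be that of the mutated gene itself. Against wild type, 12 of these 26 were higher and 7 lower in the mutant lines (15 and 7 adjusted over the list alone), and camera did not call the list (adjusted p = 0.37). DETOXIFICATION 35 FvH4_7g30023 (chromosome 7, 21961401 to 21965405) fell from 19.0 ± 1.13 in wild type to 2.36 ± 0.293 in line 1 and 1.76 ± 0.184 in line 2. DETOXIFICATION 48 FvH4_1g15940 rose from 0.714 ± 0.161 to 4.17 ± 0.571 and 5.46 ± 0.479, and DETOXIFICATION 12 FvH4_4g26362 from 4.11 ± 0.281 to 7.02 ± 0.201 and 11.9 ± 0.338. DETOXIFICATION 27 FvH4_5g36191 fell from 44.6 ± 1.15 to 28.7 ± 0.861 and 23.7 ± 0.385. In line 2 alone, 15 members were higher and 5 lower (16 and 5 adjusted over the list alone; camera adjusted p = 0.024, and adjusted p = 0.6 with an estimated correlation). That call was lost with a filter of a mean of at least 5 FPKM (adjusted p = 0.2), and over all alternatives its adjusted p lay between 0.015 and 0.2.

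Both mutant lines together were compared with wild type. The largest falls included ATHB-6 FvH4_1g20230, a homeodomain-leucine zipper transcription factor of the abscisic acid response (chromosome 1, 12443386 to 12446282), at 141 ± 12.2 FPKM in wild type. It was 0.647 ± 0.222 in line 1 and 0.910 ± 0.115 in line 2, 219-fold and 155-fold lower. FvH4_1g20221, listed nearby (chromosome 1, 12431379 to 12438254), fell as well, from 4.24 ± 0.23 to 0.0186 and 0.00577. Whether the sequence there differs between wild type and the lines was not tested. The acyl-lipid desaturase FvH4_3g44270 (chromosome 3, 36905750 to 36909440), of the type that makes polyunsaturated fatty acids, fell from 345 ± 46.5 to 11.2 ± 1.12 and 13.5 ± 0.541. ATP-citrate synthase alpha chain FvH4_3g10370 (chromosome 3, 6064957 to 6067732) stood at 25.2 ± 0.891 in wild type and at 0 in all line 1 libraries, at least 146-fold lower by a floor of 3 fragments per library. In line 2 it was 0.0168 ± 0.0290. Xyloglucan endotransglucosylase/hydrolase FvH4_3g00850, a cell wall remodelling enzyme, fell from 39.2 ± 2.19 to 5.58 ± 0.661 and 1.43 ± 0.164.

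Receptors and signalling proteins were also among the largest falls. The cysteine-rich receptor-like kinase FvH4_3g15160 dropped from 10.3 ± 0.860 to 0 in all 6 mutant libraries, at least 143-fold and 157-fold lower in lines 1 and 2. The disease resistance protein Roq1 FvH4_1g04740 fell from 6.44 ± 1.33 to 0.0441 ± 0.0128 and 0.0644 ± 0.0341. A RALF-like peptide gene, FvH4_3g09010, fell from 39.0 ± 6.29 to 3.05 ± 0.357 and 6.90 ± 0.463, and the defensin-like FvH4_5g33001 from 8.17 ± 3.16 to 0.0712 ± 0.123 and 0. DREB1D FvH4_7g28950, a transcription factor of the cold and drought response, fell from 19.5 ± 3.12 to 8.02 ± 1.77 in line 1 and 0.231 ± 0.310 in line 2. The listed falls also held FvH4_3g10331, with a Helitron helicase-like domain (11.2 ± 1.48 in wild type), and FvH4_3g10392, with a reverse transcriptase-like domain (10.8 ± 0.529 in wild type and 0 in all mutant libraries).

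Among the largest rises, beta-galactosidase 15 FvH4_1g09190 (chromosome 1, 4895374 to 4900540), of a family that trims galactose from cell wall polymers, went from 1.32 ± 0.0593 to 12.6 ± 0.759 and 43.3 ± 0.24, 9.49-fold and 32.7-fold higher. Mannitol dehydrogenase FvH4_7g07240 rose from 6.25 ± 0.236 to 30.8 ± 0.794 and 88.9 ± 2.46, and laccase-9 FvH4_2g12590, an oxidase of the lignin-forming family, from 23 ± 3.01 to 84.9 ± 8.54 and 249 ± 7.03. The acyltransferase Pun1 FvH4_4g17130 rose 15.4-fold and 13.4-fold, from 0.491 ± 0.128. KEULE FvH4_5g29992, a regulator of vesicle fusion, rose from 2.89 ± 0.580 to 18.3 ± 0.779 and 19.5 ± 0.360, and the MT-A70-like methyltransferase FvH4_2g22660 from 2.34 ± 0.317 to 16.5 ± 0.801 and 15.5 ± 1.40. The Cf-9-like receptor FvH4_7g10111 rose 7.89-fold and 9.71-fold. A polysaccharide lyase, FvH4_1g03290, rose from 5 ± 1 to 26.4 ± 0.732 and 30.4 ± 4, and FvH4_3g29670, with an XS domain, from 1.40 ± 0.417 to 16.1 ± 1.42 and 16.6 ± 0.804. A transcript outside the annotation on chromosome 2 (1031614 to 1034269), matched to RNA polymerase subunit 9B without a listed domain, rose as well. It went from 0.931 ± 0.462 to 12 ± 1.79 and 20.9 ± 1.77. FvH4_5g27492, with a reverse transcriptase zinc-binding domain, rose from 0.684 ± 0.661 to 6.74 ± 2.83 and 7.91 ± 3.05 (limma adjusted p = 0.000326, the highest among these 24 genes).

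limma called 5545 of 15890 tested genes in this comparison, 2674 higher and 2871 lower in the mutant lines, and 505 of them differed by at least 2-fold. The share of higher genes was 48.2% with the deposited scaling, 57.5% with each library rescaled to the same FPKM sum and 50.3% with voom on recovered fragments.

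**Figure D2:**
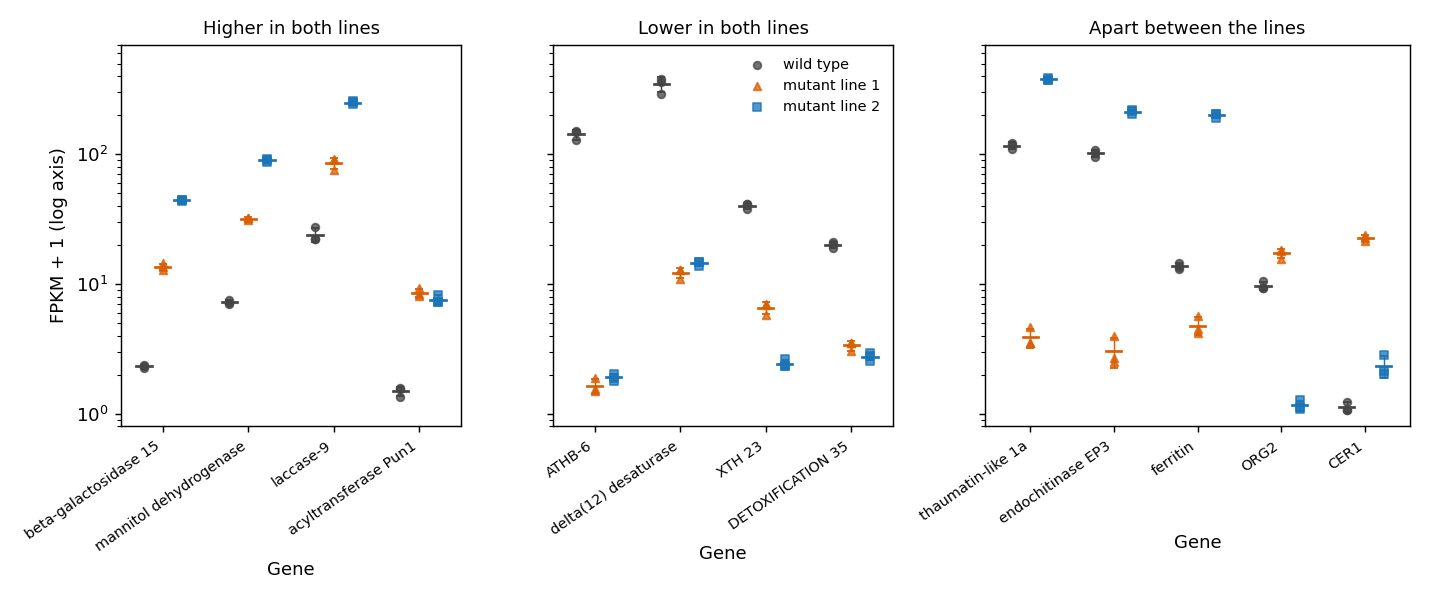
FPKM + 1 on a log axis for 13 genes (horizontal axis) in wild type (circles), mutant line 1 (triangles) and mutant line 2 (squares); points are libraries, horizontal bars group means and error bars SD (n = 3). ATHB-6 went from 141 FPKM in wild type to under 1 in both lines, and thaumatin-like protein 1a from 115 to 2.88 in line 1 and 377 in line 2.

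Cytosolic ribosomal protein genes were lower as a group. Of 181 tested, 148 fell and 6 rose (154 and 8 adjusted over the list alone), with a median log2 change of -0.41. Ribosomal protein L31 FvH4_3g43260 fell from 62.3 ± 7.90 to 38.6 ± 0.562 and 34.6 ± 2.65, and L28-1 FvH4_6g32910 from 222 ± 25.3 to 147 ± 3.33 and 144 ± 13.4. Among the 6 that rose was a copy of L27, FvH4_7g04670, which fell in line 1 and rose in line 2, at 21.8 ± 1.63 in wild type, 11.4 ± 2.15 in line 1 and 171 ± 2.34 in line 2. camera called the list (adjusted p = 2.9e-18), and the call was lost with an estimated correlation (adjusted p = 0.82). The list's mean level in wild type replicate 3, a library that stood apart, was 0.19 log2 units above the wild type mean, against -0.12 and -0.06 in the other 2 replicates. All 6 mutant libraries were lower, between -0.49 and -0.23.

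Of 65 genes of histones and the cell cycle, 32 were lower, 3 higher and 30 not called (36 and 5 adjusted over the list alone), median -0.35. Histone H3.2 FvH4_3g39201 fell from 90.5 ± 13.0 to 37.2 ± 1.03 and 35.8 ± 2.11, and histone H2A FvH4_3g02940 from 40 ± 4.26 to 18.9 ± 2.32 and 9.39 ± 1.62. The replication licensing factors MCM4 FvH4_2g09990 (11.2 ± 0.876 to 4.05 ± 0.0612 and 6.84 ± 0.0362) and MCM5 FvH4_1g01490 (28.9 ± 3.88 to 7.92 ± 0.898 and 17.7 ± 0.724) fell as well. The camera adjusted p was 6.3e-08, and adjusted p = 0.46 with an estimated correlation. Beside both groups, the seed storage and late embryogenesis list, a marker of the achenes that sit on the fruit, had 39 of 77 genes lower and 7 higher (40 and 7 adjusted over the list alone; median -0.35; camera adjusted p = 0.00022, adjusted p = 0.82 with an estimated correlation). In line 1 the seed list was not called (26 lower and 12 higher, 26 and 12 adjusted over the list alone; camera adjusted p = 0.11). The 3 members with the lowest adjusted p were NDR1/HIN1-like proteins, matched by a shared domain and named for defence signalling. Among them FvH4_6g20120 fell from 188 ± 29.0 to 106 ± 9.31 and 46.0 ± 0.851. The vicilin-like FvH4_1g13730 went the other way, from 26.7 ± 3.23 to 40.6 ± 4.21 and 94.2 ± 4.33.

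Pathogenesis-related protein genes were lower in 38 of 82 cases and higher in 8 (40 and 8 adjusted over the list alone; median -0.24; camera adjusted p = 9.8e-06, adjusted p = 0.46 with an estimated correlation). The list was called in line 1 but not in line 2, where 17 members were higher and 22 lower (17 and 24 adjusted over the list alone; camera adjusted p = 0.9). The Fra a allergen gene FvH4_4g18850 stood at 23.3 ± 6.52 in wild type, 0.174 ± 0.103 in line 1 and 21.4 ± 0.511 in line 2. Another, FvH4_4g18851, stood at 15.4 ± 2.65, 0.411 ± 0.166 and 12.4 ± 1.35. Glutathione S-transferases, which conjugate glutathione to small molecules and of which some assist anthocyanin transport, were lower in 23 of 46 cases and higher in 7 (24 and 8 adjusted over the list alone; median -0.25). F11 FvH4_1g27460 fell in both lines, from 1066 ± 122 to 574.5 ± 56.4 and 538.5 ± 40.3. The list was called lower in line 1 only: in line 2, 13 members were higher and 12 lower (13 and 15 adjusted over the list alone; median -0.02, mean 0.13; camera adjusted p = 0.94). The camera adjusted p was 0.01 (adjusted p = 0.82 with an estimated correlation), and 0.1 after correction for gene length, the highest over all alternatives, which went down to 0.0027. With that correction the median was -0.187 (21 lower, 8 higher), and the list mean went from -0.2 ± 0.07 (SE over libraries) to -0.12 ± 0.03. The call ended as the mean shrank, although it stayed below 0 by more than its spread.

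Of 67 ABC transporters, 27 were higher, 5 lower and 35 not called (29 and 5 adjusted over the list alone; median 0.23). ABC transporter C family member 8 FvH4_6g33070 rose from 6.61 ± 1.65 to 11.2 ± 0.563 and 25.3 ± 1.34, C family member 12 FvH4_3g09710 from 8.44 ± 2.35 to 14.9 ± 1.29 and 30.6 ± 1.25, and B family member 11 FvH4_4g21370 from 0.550 ± 0.209 to 2.49 ± 0.607 and 2.24 ± 0.369. The camera adjusted p was 0.0012 (adjusted p = 0.82 with an estimated correlation). It was 0.16 after correction for gene length and between 1e-04 and 0.16 over all alternatives. With no filter on low values, which adds genes near 0 to every list, the medians shrank to 0.055 for ABC transporters, -0.15 for glutathione S-transferases, -0.036 for pathogenesis-related proteins, -0.107 for seed storage and -0.082 for histones. The ABC transporter median was 0.082 after correction for gene length, where the call ended as the list mean shrank from 0.26 ± 0.1 (SE over libraries) to 0.13 ± 0.03, and 0.099 without wild type replicate 3, and that of histones -0.216 without wild type replicate 3.

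**Figure D3:**
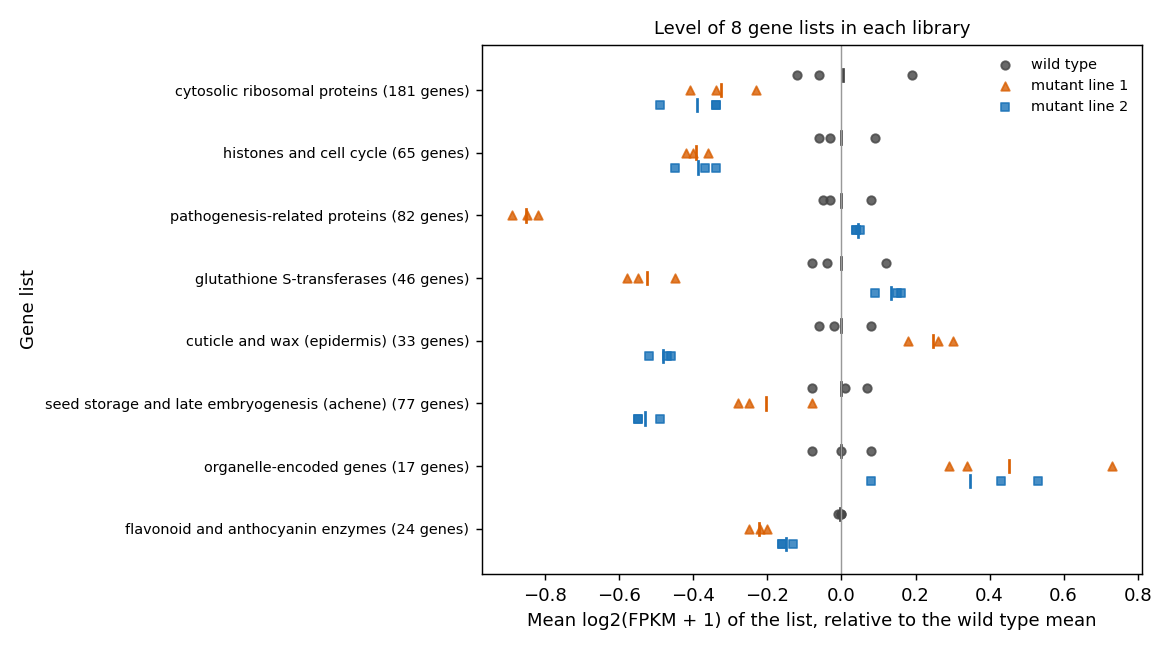
Mean log2(FPKM + 1) of 8 gene lists in each of the 9 libraries, relative to the wild type mean (horizontal axis, log2 units); circles, triangles and squares are libraries of wild type, line 1 and line 2, and vertical bars are group means (n = 3). The ribosomal protein list lay between -0.49 and -0.23 in the 6 mutant libraries, and the pathogenesis-related list between -0.89 and -0.82 in line 1 but between 0.04 and 0.05 in line 2.

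Flavonoid and anthocyanin enzymes, the pathway of fruit pigment, had 9 of 24 genes lower and 1 higher (9 and 2 adjusted over the list alone). Dihydroflavonol 4-reductase FvH4_2g39520 fell from 430 ± 19.0 to 312 ± 13.6 and 184 ± 1.40, and leucoanthocyanidin dioxygenase FvH4_5g01170 from 1374 ± 126 to 1111 ± 15.9 and 653 ± 9.19. Chalcone isomerase-like FvH4_7g25890 fell from 1255 ± 164 to 823 ± 121 and 522 ± 30.1, and anthocyanidin 3-O-glucosyltransferase FvH4_7g33840, which adds the sugar that stabilises anthocyanins, from 536 ± 31.7 to 248 ± 46.6 and 341 ± 9.02. The list as a whole was not called (camera adjusted p = 0.15). It was called with a filter of a mean of at least 5 FPKM (0.0057) and without the 2 libraries that stood apart (0.038), and its adjusted p lay between 0.0057 and 0.47 over all alternatives.

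Upstream of that pathway, phenylalanine ammonia-lyase FvH4_7g19130 rose from 42.6 ± 2.17 to 70.6 ± 11.3 and 162 ± 8.57. The more abundant phenylalanine ammonia-lyase FvH4_6g16060 stood at 298 ± 11.3, 309 ± 51.1 and 202 ± 8.97, lower in line 2 (limma adjusted p = 0.00358) and not past the test in line 1 (0.797). Of 7 phenylpropanoid entry genes 3 were higher and 0 lower (3 and 2 adjusted over the list alone). The other 2 higher ones, the 4-coumarate-CoA ligase genes FvH4_4g24170 and FvH4_4g09340, were not past the test in line 1 (limma adjusted p = 0.0639 and 0.872) and lost their call under several settings. In the lignin list 7 of 30 were higher and 6 lower (7 and 7 adjusted over the list alone). Caffeoyl-CoA O-methyltransferase FvH4_2g05780 rose from 175 ± 16.1 to 251 ± 17.2 and 443 ± 24.7, while cinnamoyl-CoA reductase FvH4_5g26020 fell from 6.35 ± 0.599 to 1.28 ± 0.259 and 1.40 ± 0.167. Carotenoid enzymes were higher in 6 of 19 cases and lower in 1 (6 and 1 adjusted over the list alone): phytoene synthase FvH4_6g38780, the entry step of carotenoid synthesis, rose from 23 ± 1.47 to 55.3 ± 1.77 and 63.4 ± 2.85. The camera adjusted p was 0.63 for phenylpropanoid entry and 0.95 for lignin. The carotenoid list was not called (camera adjusted p = 0.37) except with a filter of a mean of at least 5 FPKM (0.033), in a range of 0.033 to 0.51.

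The tonoplast dicarboxylate transporter FvH4_3g00891, which moves malate into the vacuole, fell from 239 ± 7.07 to 60.3 ± 5.17 and 65.5 ± 2.11, while 8 of 34 organic acid genes were higher and 6 lower (8 and 6 adjusted over the list alone). Sugar carrier protein C FvH4_3g03900 fell from 98.5 ± 3.21 to 37.8 ± 2.17 and 32.5 ± 2.83 and SWEET1 FvH4_2g14860 from 68.6 ± 6.05 to 26.9 ± 0.0756 and 37.4 ± 0.799, among 10 sugar transporters lower and 6 higher of 26 (11 and 7 adjusted over the list alone). Of 36 sucrose metabolism genes, 8 were higher and 1 lower (7 and 1 adjusted over the list alone). Sucrose-phosphate synthase FvH4_2g00340 rose from 3.07 ± 0.775 to 4.53 ± 0.735 and 10.1 ± 0.749, while the list also held phosphofructokinases. The sucrose list was not called (camera adjusted p = 0.08), but was with quantile normalization (0.046), without line 1 replicate 2 (0.04) and without the 2 libraries that stood apart (0.042), in a range of 0.04 to 0.28. Proton pumps of the vacuole had 6 of 22 lower and 2 higher (6 and 2 adjusted over the list alone), and aquaporins 9 of 23 lower and 5 higher (10 and 5 adjusted over the list alone). The camera adjusted p was 0.97 for organic acids, 0.46 for sugar transporters, 0.62 for proton pumps and 0.66 for aquaporins.

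In the cuticle and wax list 6 of 33 genes were higher and 9 lower (6 and 11 adjusted over the list alone). ECERIFERUM 2 FvH4_5g34850, needed for elongation of very long chain wax precursors, fell from 59.9 ± 2.78 to 11 ± 0.433 and 7.29 ± 0.627, and HOTHEAD FvH4_6g33360 rose from 12.7 ± 0.335 to 23.1 ± 1.46 and 25.2 ± 0.520. Of the cell wall softening genes 13 of 73 were higher and 26 lower (13 and 27 adjusted over the list alone). Secondary wall genes of the vascular tissue were higher in 4 of 25 cases and lower in 6 (4 and 6 adjusted over the list alone). Pollen and stamen genes, mostly expansins, were higher in 4 of 18 and lower in 9 (4 and 9 adjusted over the list alone). In the organelle list 7 of 17 were higher and 1 lower (8 and 1 adjusted over the list alone). The camera adjusted p was 0.35 for cuticle, cell wall and organelle lists, 0.93 for secondary wall and 0.4 for pollen and stamen. The organelle list held nuclear genes too, and its mean was 0.29 to 0.73 log2 units above wild type in line 1, highest in replicate 2, and 0.08 to 0.53 above in line 2. Its median went from 0.20 to 1.387 with a filter of a mean of at least 5 FPKM.

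Hormone lists held members going both ways. In the ethylene list 15 of 65 genes were higher and 15 lower (15 and 15 adjusted over the list alone): ERF026 FvH4_5g01460 fell from 5.82 ± 0.386 to 0.841 ± 0.0285 and 0.151 ± 0.0806. Auxin genes were higher in 17 of 72 cases and lower in 13 (17 and 13 adjusted over the list alone), with AUX28 FvH4_2g22520 falling from 16.9 ± 2.33 to 7.18 ± 0.709 and 8.35 ± 0.550. Gibberellin genes were higher in 4 of 13 and lower in 3 (4 and 3 adjusted over the list alone). Gibberellin 2-beta-dioxygenase FvH4_3g16760, which inactivates gibberellins, rose from 42.6 ± 1.03 to 56.8 ± 2.82 and 92.0 ± 1.17. Abscisic acid genes were higher in 3 of 24 and lower in 4 (3 and 3 adjusted over the list alone). Jasmonate genes were higher in 12 of 40 and lower in 12 (13 and 13 adjusted over the list alone). TIFY 10B FvH4_6g35140, a repressor of jasmonate signalling, fell from 37.3 ± 2.67 to 21.7 ± 1.42 and 13.3 ± 0.175.

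Of the remaining lists, aroma volatile genes were higher in 15 of 65 cases and lower in 19 (16 and 22 adjusted over the list alone), and germacrene D synthase FvH4_5g06470, an abundant terpene synthase, rose from 1137 ± 113 to 1497 ± 46.4 and 2856 ± 142. Ascorbate genes were higher in 10 of 33 and lower in 6 (10 and 7 adjusted over the list alone), and iron homeostasis genes in 8 and 10 of 31 (8 and 10 adjusted over the list alone). Heat shock genes were higher in 21 of 174 and lower in 44 (21 and 44 adjusted over the list alone). WRKY factors were higher in 10 of 35 and lower in 5 (12 and 5 adjusted over the list alone), peroxidases in 7 and 8 of 31 (8 and 8 adjusted over the list alone), and photosynthesis genes in 8 and 9 of 52 (8 and 9 adjusted over the list alone). None of the lists in this paragraph and the previous one was called by camera, with adjusted p between 0.14 for WRKY factors and 0.97 for abscisic acid and iron homeostasis. Median, mean and test had the same sign in every called list. Among lists not called they differed in sign for lignin (median -0.05, mean 0.07), organic acids (0.01 and -0.11), jasmonate (0.03 and -0.04) and aroma volatiles (-0.07 and 0.02), and the camera direction was lower beside a mean or median of 0.00 to 0.03 for iron homeostasis and secondary wall genes.

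Line 1 was then compared with wild type alone. CER1 FvH4_7g08590, an enzyme of wax alkane synthesis (chromosome 7, 8448262 to 8452398), rose from 0.124 ± 0.0996 to 21.6 ± 1.14, 174-fold, and tricyclene synthase FvH4_6g43791, a monoterpene synthase, from 0.0916 ± 0.127 to 15.3 ± 1.55. A delta-7 desaturase, FvH4_3g28040, rose from 4.81 ± 0.381 to 58.0 ± 3.21, the phosphodiesterase GDPDL3 FvH4_3g13670 from 8.89 ± 0.950 to 81.1 ± 2.80, and fatty acyl-CoA reductase FvH4_3g24570 from 1.19 ± 0.134 to 16.8 ± 0.614. ATHB-6 fell most and the acyl-lipid desaturase was also among the 5 largest falls. The other 3 were defence genes: thaumatin-like protein FvH4_6g16950 fell from 115 ± 7.36 to 2.88 ± 0.656, endochitinase EP3 FvH4_4g10610 from 101 ± 6.58 to 2.06 ± 0.801, and glucan endo-1,3-beta-glucosidase FvH4_3g28370 from 53.4 ± 5.68 to 1.04 ± 0.607. In all, limma called 2618 genes higher and 3027 lower in line 1, 693 of them by at least 2-fold. The share of higher genes was 46.4% with the deposited scaling, 61.7% with each library rescaled to the same FPKM sum and 57% with voom on recovered fragments.

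Among the lists in line 1, camera called the ribosomal proteins (107 of 181 lower and 5 higher, 135 and 5 adjusted over the list alone, adjusted p = 9.9e-12). It also called pathogenesis-related proteins (36 of 82 lower and 10 higher, 37 and 10 adjusted over the list alone, adjusted p = 5.6e-06). Histones and cell cycle genes were called lower (33 of 65 lower and 5 higher, 35 and 6 adjusted over the list alone, adjusted p = 5.6e-06), as were glutathione S-transferases (29 of 46 lower and 4 higher, 29 and 4 adjusted over the list alone, adjusted p = 1.2e-05). ABC transporters were called upward (23 of 67 higher and 6 lower, 26 and 7 adjusted over the list alone, adjusted p = 0.0074). Glutathione S-transferase U9 FvH4_5g15020 fell from 14.2 ± 2.08 to 0.201 ± 0.0999. The ribosomal median was -0.37, and -0.205 with quantile normalization. With an estimated correlation the adjusted p rose to 0.77 for ribosomal proteins and ABC transporters, 0.45 for pathogenesis-related proteins and histones, and 0.69 for glutathione S-transferases. The ABC transporter call was lost after correction for gene length (adjusted p = 0.28; median 0.093, mean from 0.23 ± 0.11 to 0.11 ± 0.03, SE over libraries) and without wild type replicate 3 (0.11; median 0.096), in a range of 0.00099 to 0.28, and with no filter on low values the pathogenesis-related median was 0 in place of -0.24. Among lists not called in line 1, median, mean and camera direction differed in sign for MATE transporters, aquaporins, cell wall, auxin, ethylene, ascorbate and pollen.

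The same comparison was made for line 2, whose leading genes were largely those given above for both lines together. Ferritin FvH4_6g10770, the iron store of plastids (chromosome 6, 6464165 to 6467043), rose from 12.7 ± 0.769 to 199 ± 8.29, 15.6-fold. Phloretin 4'-O-glucosyltransferase FvH4_4g13000, which glycosylates flavonoid-like dihydrochalcones, rose from 2.79 ± 0.510 to 48.1 ± 1.64. Beta-galactosidase 15, mannitol dehydrogenase and the transcript matched to RNA polymerase subunit 9B were the other 3 of its 5 largest rises. ATHB-6, ATP-citrate synthase, the acyl-lipid desaturase, DREB1D and xyloglucan endotransglucosylase/hydrolase were its 5 largest falls, with the values given above. limma called 2430 genes higher and 2402 lower, 747 of them by at least 2-fold. The share of higher genes was 50.3% with the deposited scaling and 46.5% with voom.

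Ribosomal proteins were lower in line 2 in 143 of 181 cases and higher in 4 (157 and 5 adjusted over the list alone; camera adjusted p = 6.8e-20), and histones and cell cycle genes in 35 of 65 and 3 (35 and 3 adjusted over the list alone; adjusted p = 1.5e-07). Of 33 cuticle and wax genes, 19 were lower and 3 higher (22 and 4 adjusted over the list alone; adjusted p = 2.2e-06). Seed storage and late embryogenesis genes were lower in 38 of 77 cases and higher in 6 (38 and 7 adjusted over the list alone; adjusted p = 3e-06), and pollen and stamen genes in 10 and 2 of 18 (11 and 2 adjusted over the list alone; adjusted p = 0.0093), with expansin-A6 FvH4_6g13610 falling from 80.2 ± 6.91 to 31.9 ± 2.38. ABC transporters were higher in 23 of 67 and lower in 4 (23 and 5 adjusted over the list alone; adjusted p = 0.0096), and sucrose metabolism genes in 11 and 2 of 36 (14 and 3 adjusted over the list alone; adjusted p = 0.036). With no filter the medians shrank from -0.49 to -0.087 for cuticle, from -0.39 to -0.135 for seed storage and from 0.42 to 0.038 for MATE transporters. With an estimated correlation the adjusted p was 0.58 for histones and cuticle, 0.6 for ribosomal proteins, seed storage, pollen and sucrose, and 0.88 for ABC transporters. The ABC transporter call was lost after correction for gene length (adjusted p = 0.19), without wild type replicate 3 (0.089) and without the 2 libraries that stood apart (0.11), in a range of 0.0014 to 0.19. The medians were then 0.04, 0.103 and 0.103, against 0.14. With the length correction the list mean went from 0.28 ± 0.1 (SE over libraries) to 0.16 ± 0.03. The sucrose call was lost after correction for gene length (adjusted p = 0.079), with no filter (0.11) and without wild type replicate 1 (0.059), in a range of 0.027 to 0.11. The medians were then 0.149, 0.055 and 0.159, against 0.17, so only the filter moved the median far. With the length correction the list mean went from 0.18 ± 0.02 to 0.14 ± 0.02. The pollen call was lost with a filter of a mean of at least 5 FPKM (adjusted p = 0.2; median -0.126), in a range of 0.0042 to 0.2. Among lists not called in line 2, median, mean and camera direction differed in sign for flavonoids, glutathione S-transferases, sugar transporters, organic acids, abscisic acid, ethylene, aroma, heat shock, pathogenesis-related proteins and peroxidases.

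Genes that moved the same way in both lines were then counted. ATHB-6, the acyl-lipid desaturase, the tonoplast dicarboxylate transporter and ECERIFERUM 2 were among 1233 genes lower in both lines, and beta-galactosidase 15, laccase-9, Pun1 and phytoene synthase among 1086 higher in both. Of these 2319 genes, 241 differed by at least 2-fold in each line. The share of higher genes was 46.8% with the deposited scaling and 55.6% with each library rescaled to the same FPKM sum. Independent lists of the same sizes would share 457.6 lower and 400.4 higher genes. A further 426 genes were called in opposite directions, 142 higher in line 1 and lower in line 2 and 284 the reverse, where independent lists would share 858.7. Both comparisons used the same 3 wild type libraries: in 100 simulations of unchanged groups the fold changes correlated across genes at r = 0.5, as observed (0.5; genes are not independent replicates), with 66.7% of genes of the same sign against 69.9% observed. The observed covariance was 0.124 against 0.0086 in the simulations, and the simulations shared 0.03 calls on average and at most 1. The 3 controls cannot be divided so that each part holds 2, so part of the excess may come from the shared controls.

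The lines differed from each other, and line 2 was compared with line 1 directly, positive values being higher in line 2. Defence genes were among the largest differences. Thaumatin-like protein FvH4_6g16950 (chromosome 6, 10815317 to 10816866), an antifungal protein family, stood at 115 ± 7.36 in wild type, 2.88 ± 0.656 in line 1 and 377 ± 8.21 in line 2. The lines were 131-fold apart by mean FPKM, and the log2 difference of FPKM + 1 was 6.62 (limma adjusted p = 1.41e-10). Endochitinase EP3 FvH4_4g10610 was 102-fold higher in line 2 (211 ± 7.81 against 2.06 ± 0.801), and basic secretory protease FvH4_2g05020 154-fold (64.0 ± 0.598 against 0.414 ± 0.159). The Fra a allergen gene FvH4_4g19040 was 73-fold higher (85.1 ± 5.07 against 1.17 ± 0.214) and the glucanase FvH4_3g28370 63.9-fold (66.7 ± 4.68 against 1.04 ± 0.607). PR-4A FvH4_3g05950, of the Barwin family, stood at 27.1 ± 2.46 in line 2, 0.120 ± 0.0478 in line 1 and 11 ± 1.83 in wild type. Of 82 pathogenesis-related genes, 32 were higher and 20 lower in line 2 (32 and 22 adjusted over the list alone; mean log2 0.90, median 0.04; camera adjusted p = 0.0056, adjusted p = 0.64 with an estimated correlation). The median ranged from -0.043 with libraries rescaled to the same FPKM sum, and -0.035 with voom, to 0.284 with a filter of a mean of at least 5 FPKM (adjusted p = 2.1e-05). It was -0.022 with no filter, where the call was also lost (0.41, the highest of a range from 2.1e-05).

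Other genes with large differences between the lines came from several processes, and the iron homeostasis list was not called (10 of 31 higher and 8 lower, 11 and 8 adjusted over the list alone; camera adjusted p = 0.51). Ferritin FvH4_6g10770 stood at 199 ± 8.29 in line 2 and 3.78 ± 0.767 in line 1, 52.6-fold apart, and ORG2 FvH4_2g11650, a transcription factor of the iron deficiency response, at 0.161 ± 0.104 and 16.3 ± 1.46, with 8.71 ± 0.680 in wild type. The delta-7 desaturase FvH4_3g28040 was 40.2-fold lower in line 2 than in line 1, CER1 FvH4_7g08590 16.2-fold, and tricyclene synthase and the fatty acyl-CoA reductase were at 0.0457 ± 0.0519 and 0.639 ± 0.0486 in line 2. Prunin FvH4_2g21400, a seed storage globulin, stood at 136 ± 57.6 in wild type, 135 ± 90.6 in line 1 and 18.9 ± 16.6 in line 2. Of the cuticle and wax genes 21 of 33 were lower in line 2 and 2 higher (21 and 4 adjusted over the list alone; median -0.67; camera adjusted p = 1.7e-08, adjusted p = 0.2 with an estimated correlation), among them 3-ketoacyl-CoA synthase FvH4_4g27420 (1.34 ± 0.474 against 9.28 ± 1.25) and acyltransferase FvH4_6g11850 of cutin synthesis (3.16 ± 0.130 against 14.4 ± 0.841). Beside it, seed storage and late embryogenesis genes were lower in 32 of 77 cases and higher in 15 (38 and 19 adjusted over the list alone; median -0.31; adjusted p = 0.0062). Secondary wall genes of the vascular tissue were lower in 9 and higher in 1 of 25 (10 and 1 adjusted over the list alone; median -0.27; adjusted p = 0.0011) and pollen and stamen genes in 7 and 2 of 18 (8 and 2 adjusted over the list alone; median -0.17; adjusted p = 0.0077). All 3 had adjusted p = 0.64 with an estimated correlation. With no filter the medians shrank to -0.159 for cuticle, -0.117 for seed storage and -0.069 for secondary wall genes, and all 3 calls held. The pollen call was lost with a filter of a mean of at least 5 FPKM (adjusted p = 0.35; median -0.106), in a range of 0.0048 to 0.35. Its median was -0.262 with TPM scaling, -0.302 with voom and -0.068 with no filter, and the list was called under all 3.

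Glutathione S-transferases were higher in line 2 in 21 of 46 cases and lower in 6 (22 and 7 adjusted over the list alone; median 0.29; camera adjusted p = 0.00033, adjusted p = 0.64 with an estimated correlation): U9 FvH4_5g15020 stood at 30.1 ± 1.01 against 0.201 ± 0.0999. Jasmonate genes were higher in 16 of 40 and lower in 4 (17 and 5 adjusted over the list alone; median 0.14; adjusted p = 0.0029, and adjusted p = 0.2 with an estimated correlation). Jasmonate-induced oxygenase FvH4_2g07081 stood at 309 ± 17.1 against 28.1 ± 2.68, and 12-oxophytodienoate reductase FvH4_1g08454, of the jasmonate synthesis family, at 6.71 ± 0.840 against 0.119 ± 0.0777. Organic acid genes were higher in 14 of 34 and lower in 4 (14 and 4 adjusted over the list alone; median 0.23; adjusted p = 0.015, and adjusted p = 0.64 with an estimated correlation). Aroma volatile genes were higher in 21 and lower in 2 of 65 (24 and 3 adjusted over the list alone; median 0.18; adjusted p = 0.023, and adjusted p = 0.2 with an estimated correlation). Ribosomal proteins were higher in 3 and lower in 10 of 181 (2 and 4 adjusted over the list alone; median -0.08; adjusted p = 0.019, and adjusted p = 0.87 with an estimated correlation). The jasmonate call was lost with a filter of a mean of at least 5 FPKM (0.054; median 0.12, in a range from 0.00055). Without line 1 replicate 2, line 2 replicate 3 or any filter the organic acid call was lost (0.055, 0.056 and 0.097; medians 0.146, 0.234 and 0.037, in a range from 0.00034), and so was the ribosomal call (0.25, 0.28 and 0.08, in a range from 1.2e-05), which was also lost without the 2 libraries that stood apart (0.12). The ribosomal median was -0.071 with no filter and -0.033 in the other cases. It was larger in size, and the list stayed called, with TPM scaling (-0.174), voom (-0.168) and quantile normalization (-0.155). With no filter the medians were 0.148 for glutathione S-transferases, 0.02 for jasmonate, 0.037 for organic acids and 0 for aroma volatiles. With TPM scaling they were 0.058 for jasmonate, 0.139 for organic acids and 0.099 for aroma volatiles, each list still called. With voom they were 0.069 for jasmonate and 0.11 for aroma volatiles. The glutathione S-transferase median was 0.155 with a filter of a mean of at least 5 FPKM. The aroma call was lost without line 2 replicate 3 (0.061; median 0.18) and with no filter (0.12), in a range from 0.0088. Among lists not called between the lines, median, mean and camera direction differed in sign for flavonoids, sugar transporters, auxin, ascorbate and histones.

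Single MATE transporters differed between the lines, while the list was not called. A second DETOXIFICATION 35 gene, FvH4_7g30080 (chromosome 7, 21995481 to 21998809), stood at 54.4 ± 0.539 in wild type, 26.7 ± 1.11 in line 1 and 174 ± 4.41 in line 2. DETOXIFICATION 40 FvH4_6g43220 was at 2.73 ± 0.186, 0.113 ± 0.0950 and 3.44 ± 0.113, and DETOXIFICATION 33 FvH4_2g40430 at 35.5 ± 1.32, 36.2 ± 1.30 and 13.4 ± 1.45. Of the 26 tested MATE genes, 11 were higher and 4 lower in line 2 than in line 1 (12 and 6 adjusted over the list alone; camera adjusted p = 0.056). In all, limma called 2453 genes higher and 1937 lower in line 2, 744 of them by at least 2-fold. The share of higher genes was 55.9% with the deposited scaling, 40.6% with each library rescaled to the same FPKM sum and 41.7% with voom on recovered fragments. With weights estimated per library the count was 7191.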

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

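The tests on ribosomal proteins, on families of defence genes and on genes near 0 were chosen after the result was seen, as were the division by family and its bounds, the bound for family sums being changed once more after that; leaving out single libraries and the regroupings were set beforehand.

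Line 2 differed from line 1 in 4390 genes by the direct test. The list medians that differed were 0.29 for glutathione S-transferases, 0.23 for organic acids, 0.18 for aroma volatiles, 0.14 for jasmonate, 0.04 for pathogenesis-related proteins, -0.08 for ribosomal proteins, -0.17 for pollen and stamen, -0.27 for secondary wall genes, -0.31 for seed storage and -0.67 for cuticle and wax (log2, line 2 minus line 1). None of these lists was called by camera with an estimated correlation (adjusted p = 0.2 to 0.87). The 0.04 ranged from -0.043 to 0.284 over the settings and was below 0 under 3, and the call of ribosomal proteins was lost under 4. Of the genes named for their size of change and the 5 MATE genes with the lowest adjusted p, 25 differed, list examples not being included. Line 2 was higher for thaumatin-like FvH4_6g16950 (log2 6.62), endochitinase FvH4_4g10610 (6.14), protease FvH4_2g05020 (5.53), ferritin FvH4_6g10770 (5.40), allergen gene FvH4_4g19040 (5.32), glucanase FvH4_3g28370 (5.09) and glucosyltransferase FvH4_4g13000 (3.94). It was also higher for FvH4_7g30080 (2.66), FvH4_6g43220 (2.00), FvH4_7g01040 (1.93) and FvH4_4g26362 (0.69), which are 4 of those 5 MATE genes. The same held for beta-galactosidase FvH4_1g09190 (1.71), laccase FvH4_2g12590 (1.54), mannitol dehydrogenase FvH4_7g07240 (1.5), RALF-like FvH4_3g09010 (0.97) and the transcript matched to RNA polymerase subunit 9B (0.76). Line 2 was lower for FvH4_3g28040 (-4.62), FvH4_6g43791 (-3.96), ORG2 FvH4_2g11650 (-3.90), FvH4_3g24570 (-3.44), CER1 FvH4_7g08590 (-3.29), prunin FvH4_2g21400 (-2.92), DREB1D FvH4_7g28950 (-2.88), FvH4_3g13670 (-2.29) and FvH4_3g00850 (-1.43). Among MATE genes outside those 5, FvH4_2g40430 (-1.37) and FvH4_5g36191 (-0.27) were lower in line 2.

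Outside the listed genes, line 1 libraries held 4.59, 10.14 and 4.49% of the fragments, above the highest wild type value of 3.71%. These fragments are not analysed here.

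Of 82 pathogenesis-related genes, 52 differed between the lines, 32 higher and 20 lower in line 2, and in line 1 the list mean was 0.82 to 0.89 below wild type, with a median of -0.24 and 36 genes not called (log2). A single library was argued against, since at least 44 were called whichever of the 9 was left out. Fragments assigned to another near-identical copy of similar length would leave a family's summed FPKM about unmoved. Such reassignment was argued against for thaumatins (summed FPKM 2.04-fold higher in wild type than in line 1), chitinases (1.96-fold) and glucanases (1.44-fold, 513 ± 17.6 against 357 ± 34.8, SD). Each sum differed by more than 2 SE with no overlap of libraries, while a first bound of 1.5-fold had left glucanases open. Reassignment could still account for changes among the Bet v 1 family, whose sum was 1.13-fold apart with 83.5% of it in FvH4_4g32700 and whose libraries overlapped. Fragments left uncounted because they match several copies would lower a sum. The test does not cover them, since how such fragments were counted is not known. A response of line 1 plants, or a difference in their surroundings, stays open and was not tested.

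Ribosomal protein transcripts were lower in both lines, with a median of -0.41. Gene length as the whole cause was argued against: with its trend removed the median was -0.3, and the mean difference went from -0.36 ± 0.10 (SE) to -0.27 ± 0.05. The authors' scaling was argued against, the median nearest 0 under 3 other scalings being -0.28. A smaller share of achenes in the mutant samples was neither shown nor argued against. Storage and oil body genes (13, of which 2 are trafficking genes caught by name) had a median of -0.29 in line 1 and -0.99 in line 2. Of these, 2 were called lower and 1 higher in line 1, against 10 and 1 in line 2. The seed storage globulin prunin FvH4_2g21400 was not matched by name and is not among them. The ribosomal medians lay nearer each other, at -0.37 and -0.45. In line 1 the mean of the storage and oil body genes was 0.08 above that of the ribosomal proteins. Its SE of 0.27 was too wide to tell, and an effect of the mutation stays open as well.

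In wild type 21 genes were at 2.5 FPKM or more and under 0.5 in both lines, against 1 the other way, FvH4_4g29311, a gene picked out after its values were seen. Low depth was argued against, since every mutant library would hold at least 58 fragments of each at the wild type level. Sequence differences between the wild type and both lines in shared segments may account for a run of 5 genes on chromosome 3 (6037670 to 6098666), among them ATP-citrate synthase FvH4_3g10370: 4 neighbouring pairs lay within 100 kb, against 0.205 in a permutation test of 10000 random draws (permutation p = 1e-04, the smallest possible) and 1.344 in draws from 80 genes that fell but stayed expressed (permutation p = 0.037). All 4 pairs came from that run, noticed before it was tested, and the other 16 genes had 0 within that window. The test does not cover wider spacing: FvH4_3g15160 (9418429 to 9420429) and a transcript outside the annotation (6311062 to 6313573) also lay on chromosome 3. On chromosome 1, FvH4_1g20221 (12431379 to 12438254) lay near ATHB-6 (12443386 to 12446282), which passed 0.5 FPKM in mutant libraries and was not counted. Sequence differences were not tested for these genes. Local silencing or shared regulation would look alike, and those 80 genes also lay close together (14 pairs against 3.149).

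Whether chance can be excluded was asked by regrouping the libraries. For both lines against wild type, 1 of 100 groupings gave as many genes, the real one (5545, highest other 2232). For genes changed the same way it was also 1 of 100 (2319, highest other 988). A random division of these 9 libraries thus seldom gives such counts. If the replicates of a group are technical repeats, the real grouping would come first whatever the mutation did, so chance is not excluded. Chance differences between plants were not tested. Whether the other groupings with high counts keep part of the real groups together was not tested. For line 1 (5645), line 2 (4832) and between the lines (4390), the 10 splits are too few for a share under 0.05, and the highest other gave 0.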

How the results depend on the processing

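The tests with voom, with gene length correction and without the 2 libraries that stand apart were chosen after the result was seen. Counts of called genes stayed within 1.5 times the reported ones under the settings run, with 2 exceptions. Array weights gave 7191 genes between the lines, a setting that down-weights the libraries standing apart, and the cause was not tested. Requiring at least a 2-fold change gave, by construction, 505 genes for both lines against wild type, 693 for line 1, 747 for line 2, 744 between the lines and 241 changed the same way. Similar counts did not always hold the same genes. With TPM scaling, 4719 of the 5645 genes reported for line 1 and 3680 of the 4390 between the lines were called again.

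Leaving out 1 library at a time gave 4410 genes (without wild type replicate 3) to 5843 for both lines, 4177 to 5382 for line 1, 3344 to 5303 for line 2, 3289 to 5335 between the lines and 1650 to 2439 the same way. Without both libraries that stand apart the counts were 5752, 5964, 5666, 5962 and 2655. With the replicate number as a block they were 4672, 4668, 4019, 3794 and 1817. The replicate numbers do not pair the samples: deviations of libraries with the same number correlated across genes between -0.26 and 0.16. Using only the groups compared gave 4297, 4685, 4840 and 1881, with no value for both lines together, which use all 9 libraries. The median of all genes lay at most 0.09 from 0 (log2) under other scalings.

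Named genes kept their direction in every setting run, on the same side of the threshold in 3974 cases and past it no longer in 28, which concerned FvH4_4g24170, FvH4_4g09340 and FvH4_7g01040. Gene lists were the same in 1199 cases, newly called in 6 and, without a change of sign, no longer called in 23. These are given beside the lists. In 3 cases the median of the pathogenesis-related list changed sign, all between the lines: to -0.022 with no filter, where genes near 0 enter the list, to -0.043 with TPM scaling and to -0.035 with voom, against 0.284 with a filter of a mean of at least 5 FPKM. With no filter its call between the lines was lost as well (camera adjusted p = 0.41), a loss not among those 23. With no filter its median was 0 in line 1, where the list was still called (17 higher, 37 lower, camera adjusted p = 0.037). With TPM scaling and with voom the median of all tested genes between the lines moved likewise, from 0.01 to -0.07. The change of sign under those 2 settings was therefore not particular to this list. Of the 27 lists not called for both lines, 20 had a median that changed sign under some setting (70 cases, each with a reported median of at most 0.16 in size).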

Other observations

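The tests reported here as counts at a high and a low limit were chosen after the result was seen, and the genes named in them were chosen after their values were seen. In line 1 alone, 15 transcripts were under 0.5 FPKM that were at 2.5 FPKM or more in wild type and line 2. They included allene oxide synthase FvH4_5g16260 (5.22 ± 0.997 in wild type, 0.270 ± 0.0507 in line 1 and 4.58 ± 0.384 in line 2, SD, n = 3), an enzyme of jasmonate synthesis, the cytochrome P450 FvH4_2g22170 (6.66 ± 0.597, 0.446 ± 0.0434 and 13.3 ± 0.360), a chitinase FvH4_2g31570 (7.07 ± 1.05, 0.437 ± 0.0233 and 15.8 ± 0.879) and norbelladine synthase-like FvH4_7g34120 of the Bet v 1 family (4.05 ± 0.574, 0.190 ± 0.0351 and 17.1 ± 1.64). By the same limits the only transcript on in line 1 alone was tricyclene synthase FvH4_6g43791. In line 2 alone 2 were off, ORG2 and the spindle protein TPX2 FvH4_5g28561 (7.13 ± 1.61, 4.17 ± 0.909 and 0.190 ± 0.0955), and 1 was on, the amino acid transporter FvH4_2g37650 (0.382 ± 0.0936, 0.0694 ± 0.0352 and 3.51 ± 0.654).

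Within the chromosome 3 run of genes near 0 in both lines, the wall-associated receptor kinase FvH4_3g10360 went the other way. It lay between 0.05 and 0.15 FPKM in wild type libraries and between 0.86 and 2.54 in mutant libraries. Oleosin genes, picked out after their values were seen, did not all differ between the lines. FvH4_7g26900 was lower in line 2 than in line 1 (limma adjusted p = 0.000607), at 41.2 ± 8.76 FPKM in wild type, 31.0 ± 10.4 in line 1 and 8.36 ± 3.56 in line 2, and so was FvH4_5g05960 (limma adjusted p = 0.0014), at 21.5 ± 5.18, 15.1 ± 5.02 and 5.18 ± 1.32. FvH4_2g35150, at 1.24 ± 0.271 in line 1 and 1.32 ± 0.202 in line 2, was not past the test (limma adjusted p = 0.792). Across genes, log2 change rose with gene length for both lines against wild type (Spearman 0.26) and little between the lines (0.04).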
